A study of Mus musculus with 13 samples.

How the data were processed

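The series holds RNA-seq of 13 primary mammary tumour cell lines of the mouse strain FVBN/J, 6 labelled wild type (WT) and 7 labelled JNK knockout. JNK is the c-Jun N-terminal kinase family, encoded in the mouse by Mapk8, Mapk9 and Mapk10. Per the labels' protocols, cells were taken from tumours into culture on collagen I with low serum, moved after early passages to standard dishes with fetal bovine serum, EGF and insulin, and total RNA was extracted with a column kit and a DNase step. Paired-end libraries were sequenced on an Illumina NovaSeq instrument. Each sample is a separate line. The labels give no batch, no pairing of lines across the groups and no passage number. They do not say which JNK genes or exons were removed, nor whether WT replicates 4 and 5, whose titles share a number, came from the same animal. Where lines share an animal, p-values measure only the spread between these lines. The titles of the WT and knockout lines start with different letters, so any difference of colony or of handling tied to them cannot be told apart from the genotype.

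The deposited values were expected counts per gene, which the authors made with RSEM after trimming with cutadapt, per the submitters' processing notes. The genome builds named in those notes are mm10 and GRCm38. The aligner, the annotation release and all tool versions are not given in the sources used here. The authors also deposited TPM, transcript abundances scaled for length to a common sum, for the same genes and lines, made by RSEM per the submitters' processing notes. Both tables held 23845 genes by symbol, and no symbol occurred more than once. RSEM shares reads that match several genes among them by a model, so values of near-identical genes (Krt6a and Krt6b, the Sprr2 family, the histocompatibility genes, Ftl1 and its pseudogenes, ribosomal protein genes) are uncertain. Strand use in the counting is not given in the sources used here, so overlapping antisense genes were not separated. Gene positions are those of the RefSeq annotation of GRCm38, found by symbol for 12373 of the 13058 genes tested.

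The main test used the expected counts rounded to whole numbers. Genes with enough reads for a test were kept with edgeR's filterByExpr (13058 genes), libraries were scaled by TMM, and the groups were compared with edgeR's quasi-likelihood F test with the group as the only term (edgeR 4.0.16 in R 4.3.3). P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. The standard error (SE) of a log2 fold change was taken as its size divided by the square root of F and is approximate. CPM values are counts scaled to a common size of the TMM-scaled library. Log2 fold changes are knockout minus WT. A fold of a gene with very few reads in a group depends on the small count that edgeR adds, so CPM values are given for such genes. Where a group had 0 reads, the fold is a lower bound against a floor of 3 reads over that group, which covers counting error only.

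Before the data were examined, 36 gene lists, the alternatives and a rule for the genes named in the text were fixed. The rule took Mapk8, Mapk9, Mapk10 and Erbb2, the 8 genes with the largest increase and the 8 with the largest decrease among changed genes with an absolute log2 fold change of at least 1 and a mean of at least 5 CPM, and up to 4 changed members of each list with the lowest adjusted p (or the 2 members with the smallest p where none had changed). Predicted genes without a proper symbol were left out. This gave 96 genes. Other genes named in the text were chosen after their values were seen, including members of a list beyond the first 4. A list was tested where at least 5 members had been tested. This left 30 lists, since 5 lists of other cell types fell under that minimum and the list of sex-linked genes served as a check only. Lists were compared with all other genes by camera with a preset correlation between genes of 0.01 (limma 3.58.1), two-sided, with Benjamini-Hochberg adjustment over the 30 lists. Each list test was repeated with a correlation estimated from its own genes and with fry, which does not compare a list with other genes. Counts of changed members are given over all genes tested and adjusted over the list alone.

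Distances between lines were Euclidean distances of log2 CPM (prior count 2) over the 500 most variable genes. Groups were compared by an exact permutation test, two-sided, over all 1716 splits of 13 lines into 7 and 6. No pair of libraries agreed within sampling noise. The closest pair, WT replicates 1 and 6, still differed by a chi-square of 77.5 per gene.

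The alternatives fixed in advance were DESeq2 size factors, upper-quartile scaling or library size alone, DESeq2 1.42.0, limma-voom with and without sample weights, robust empirical Bayes, no filter or a stricter filter (CPM above 1 in at least 6 lines), a threshold of 0.01, a minimum absolute log2 fold change of 1, limma on log2(TPM + 1) and log2(TPM + 0.1), 1 surrogate variable (sva 3.50.0), WT replicates 4 and 5 summed, each line left out in turn, and for distances 2000 or all genes, log2(TPM + 1) and rank correlation. A fit without WT replicate 3 and knockout replicate 2, the lines farthest from their groups, was added after the data were seen. So were a test of the JNK pathway list without Mapk8 and Mapk9, and a fit in which the trend of each library with gene length was removed through offsets. Relative gene length for that fit came from the ratio of the deposited expected counts to the deposited TPM in libraries with at least 50 reads of the gene, and could be had for 12735 genes (97.5% of those tested).

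The scripts were tested on 5 sets of simulated counts for the 13058 genes of this comparison, drawn with the means, library sizes and dispersions of the real libraries, with 200 genes changed in each. Of the genes changed by 2, 4 and 8 times, 28.0%, 77.5% and 84.4% were called, and none with the wrong sign. Calls among 64290 unchanged genes numbered 15. The list test called 5 of 5 lists that had been changed and 0 of 100 that had not. Those simulated genes were independent of each other, unlike real ones. Figures were drawn with matplotlib 3.10.9.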

Results

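RNA-seq expression profiles were compared between 6 WT and 7 JNK knockout lines derived from mouse mammary tumours, in a study of JNK in HER2-driven breast cancer. HER2 is the receptor tyrosine kinase encoded by Erbb2. Expected counts summed to between 38298600 and 46689800 per line, and between 12595 and 13434 genes per line had at least 10 counts, so depth differed little between lines. Each sample was a separate line, and the spread among lines of a group was large, with a biological coefficient of variation of 0.548 over all genes. All lines held Xist at 402 to 910 CPM and 0 reads of Ddx3y, Eif2s3y, Kdm5d and Uty.

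The genes for the JNK kinases were examined first, as a check of the genotype labels. Mapk8, which encodes JNK1 (chromosome 14, 33377898 to 33447353), was 29.8 ± 5.38 CPM in WT lines (SD, n = 6) and 5.76 ± 1.32 CPM in knockout lines (SD, n = 7), a log2 fold change of -2.37 (SE 0.19, adjusted p = 9.1e-05). Mapk9, which encodes JNK2 (chromosome 11, 49846728 to 49886421), was 60.0 ± 6.59 CPM in WT lines and 19.3 ± 5.11 CPM in knockout lines, a log2 fold change of -1.63 (SE 0.19, adjusted p = 0.00091). For both genes each of the 7 knockout lines lay below every WT line. Mapk10, which encodes JNK3, had 14 reads over the WT lines and 9 over the knockout lines, and was not tested. The remaining reads of Mapk8 amounted to 19.3% of the WT mean. Since the removed exons are not known, transcripts that lack an exon can still be counted, and gene counts do not measure loss of the protein. Erbb2 (chromosome 11, 98412484 to 98437716) was 212 ± 29.4 CPM in WT and 131 ± 55.6 CPM in knockout lines, and this difference did not pass the test (log2 fold change -0.69, SE 0.25, adjusted p = 0.10). All knockout lines but replicate 6, at 228 CPM, lay below every WT line (at least 183 CPM), so a lower level in most knockout lines is not excluded. The labels do not say whether reads of an Erbb2 transgene would be counted under this symbol.

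**Figure D1:**
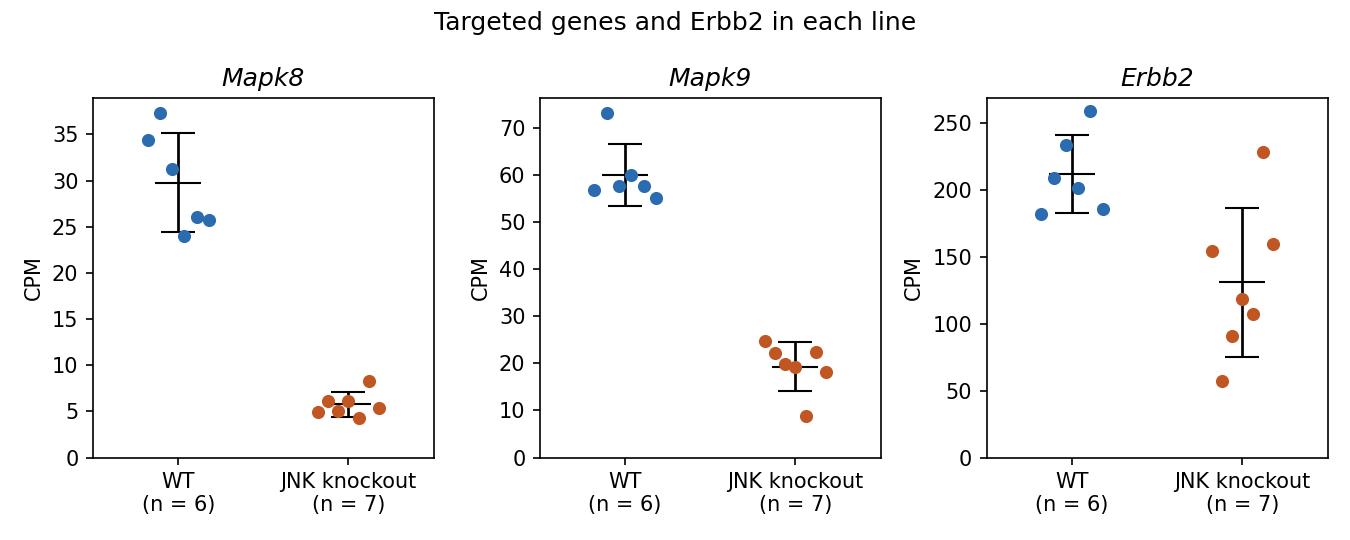
CPM of Mapk8, Mapk9 and Erbb2 in each line (points), with the mean and SD of the 6 WT and 7 JNK knockout lines (bar and whiskers, axes from 0). All 7 knockout lines lie below all 6 WT lines for Mapk8 and Mapk9.

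The lines separated by genotype over the whole transcriptome. The first principal component, with 38.5% of the variance of the 500 most variable genes, had negative values in all 6 WT lines and positive values in all 7 knockout lines. The mean distance between lines of different groups was 102, against 71.7 among knockout lines and 76.1 among WT lines. Between-group distance exceeded within-group distance by 28.8, and no other split of the 13 lines gave as large a value (exact permutation p = 0.00058, the smallest these splits can give). Every line had its highest rank correlation with a line of its own group. The groups did not differ detectably in how much their lines varied (difference of mean distance, knockout minus WT, -4.35, exact permutation p = 0.70), and the sign of that difference turned when WT replicate 1, 2 or 3 was left out or all tested genes were used. Knockout replicate 2 lay farthest from its group, with a mean distance of 90.1 to the other knockout lines.

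**Figure D2:**
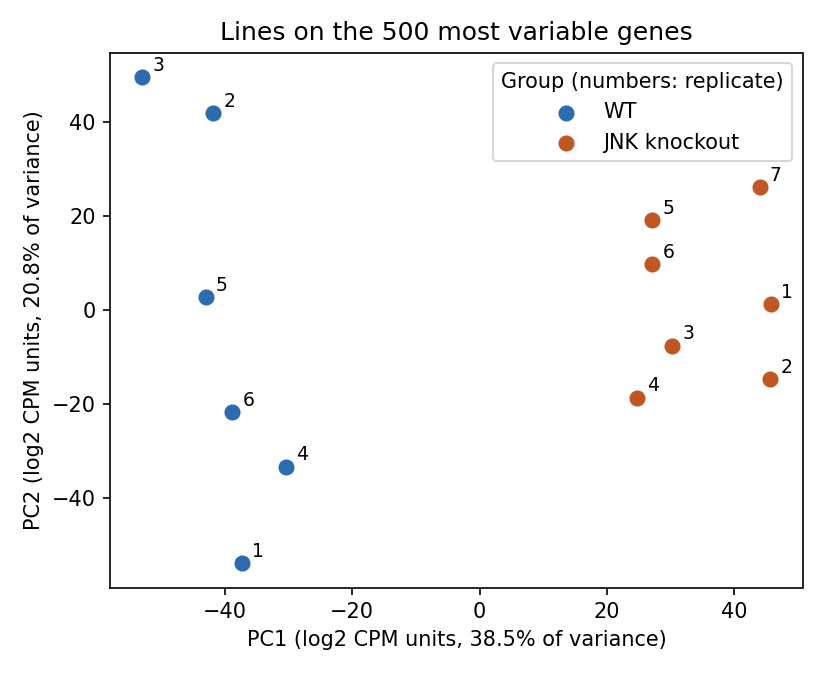
Positions of the 13 lines on the first and second principal components of log2 CPM of the 500 most variable genes (38.5% and 20.8% of the variance), numbered by replicate. WT and knockout lines fall on opposite sides of 0 on the first component, and WT lines spread along the second.

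Of 13058 genes tested, 566 were higher and 545 lower in knockout lines at an adjusted p under 0.05 (8.51% of genes), and 312 and 363 of them changed at least by a log2 fold change of 1. For 473 of the 1111 changed genes the groups did not overlap. Over all tested genes 529 (4.05%) did not overlap, where chance gives 0.117%. Of the 8 largest increases 3 were in keratin genes. Krt6a, a keratin of activated epidermis, was 0.0606 ± 0.0641 CPM in WT and 671 ± 724 CPM in knockout lines, Krt5, a basal keratin, 0.564 ± 0.365 against 2518 ± 4465 CPM, and Krt6b 0.0271 ± 0.0562 against 66.2 ± 83.4 CPM. Col17a1, a collagen of hemidesmosomes, had 48 reads over the WT lines and 82190 over the knockout lines. Similar contrasts were seen for Serpinb10 (4 and 8091 reads), the homeobox gene Pitx1 (24 and 38195), the desmosomal cadherin gene Dsc3 (5 and 6937) and Dmkn (18 and 11868), which encodes the epidermal protein dermokine. The adjusted p of these 8 genes ranged from 0.00013 for Dmkn to 0.0096 for Dsc3. With limma-voom 5 of the 8 were not called (Krt5, Krt6b, Col17a1, Serpinb10 and Dsc3, adjusted p from 0.053 to 0.13), nor was Dsc3 on log2(TPM + 1). Knockout replicate 2 contributed much to some of them. Without it the log2 fold change of Krt5 was 10.6 in place of 12.1, of Col17a1 8.99 in place of 10.7, of Serpinb10 8.77 in place of 10.7, of Krt6a 12.8 in place of 13.3 and of Krt6b 10.5 in place of 11.1. Where the few WT reads came mostly from 1 line, leaving it out raised the log2 fold change, to 15.5 from 10.5 for Pitx1 (WT replicate 4), 13.1 for Krt6b (WT replicate 2), 11.9 for Serpinb10 (WT replicate 6) and 11.02 from 10.15 for Dsc3 (WT replicate 1). Dsc3 was 144 CPM in knockout replicate 2 and between 0.027 and 14.6 CPM in the other knockout lines. Of 13 fits that left out 1 line, 7 could test Dsc3. In the others, among them that without knockout replicate 2, too few lines had reads of it. Without both knockout replicate 2 and WT replicate 3 the log2 fold change of Dsc3 was 7.77 (adjusted p = 0.014).

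The 8 largest decreases were in Chodl, Igfals, Col1a2, Rtn1, Trpm3, Dpysl5, Kctd12b and Ikzf1, with adjusted p from 0.0079 for Kctd12b to 0.031 for Ikzf1. With limma-voom 7 of the 8 were not called, all but Rtn1 (adjusted p from 0.14 to 0.32), and on log2(TPM + 1) Col1a2, Trpm3, Dpysl5 and Ikzf1 were not. DESeq2 gave no adjusted p for Col1a2 and Rtn1. These genes were high in some WT lines and not in others. Col1a2, a chain of type I collagen, was 160 CPM in WT replicate 3 and between 0.472 and 12.4 CPM in the other WT lines, against 0.282 ± 0.201 CPM in knockout lines. Chodl was 24.0 ± 25.9 CPM in WT and 0.187 ± 0.268 CPM in knockout lines, and Kctd12b had 13163 reads over the WT lines and 204 over the knockout lines. Rtn1 was below every WT line in all 7 knockout lines. Without WT replicate 3 the log2 fold changes were -3.80 in place of -6.72 for Col1a2, -4.26 in place of -6.63 for Rtn1, -4.45 in place of -6.27 for Dpysl5, -4.99 in place of -6.61 for Trpm3 and -5.91 in place of -6.96 for Igfals. That of Chodl was -6.33 in place of -7.00 without WT replicate 4, and that of Rtn1 -7.34 without knockout replicate 7. Ikzf1 kept its call in 7 of the 11 fits that left out 1 line and could test it, and was at -5.17 in place of -6.22 without WT replicate 3 (adjusted p = 0.061). With WT replicates 4 and 5, whose titles share a number, summed into 1 sample, 405 genes were higher and 406 lower. Of the 90 named genes that changed, 14 were not called in that fit (Krt8, Jag2, Atf3, Epgn, Nt5e, Foxf2, Ifit2, Irf9, B2m, Nlrc5, Bad, Atg16l2, Notum and Dhcr7). With limma-voom 34 of the 90 were not called, the 12 above and 22 others (Adamts1, Atf3, B2m, Col1a1, Dll1, Epgn, Etv5, Foxf2, H2-DMb1, Ifih1, Ifit2, Il1a, Il33, Inhbb, Irf9, Jag2, Mmp24, Muc1, Nlrc5, Notum, Tgfbi and Tslp). The count of changed genes depended on single lines. It was 374 higher without WT replicate 1, 329 higher and 316 lower without knockout replicate 1, 375 higher without knockout replicate 3, and 324 higher and 326 lower without knockout replicate 7. Chromosome 4 held 113 and chromosome 11 held 81 of the 566 higher genes, and chromosome 2 held 81 of the 545 lower genes. Fold changes were also lower for longer genes, most of all in knockout replicate 5.

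Basal and myoepithelial markers rose as a list in the knockout lines with the preset correlation. Of 23 tested members 11 rose and 0 fell (15 rose and 2 fell adjusted over the list alone), with a median log2 fold change of 3.29 (adjusted p = 2.0e-08, and 0.36 with an estimated correlation). The median was 2.68 without knockout replicate 2 and 3.95 without WT replicate 3. Krt14, the partner of Krt5 in basal epithelial cells, was 113 ± 66.7 CPM in WT and 2836 ± 2590 CPM in knockout lines (log2 fold change 4.65, SE 0.68, adjusted p = 0.0026) and was higher in all 7 knockout lines than in any WT line. Other risen members were Trp63, the transcription factor p63 of basal cells, the keratins Krt16 and Krt17, the laminin chain Lama3, P-cadherin (Cdh3) and the Notch ligand Jag2. The contractile members Acta2, Tagln, Myh11, Mylk and Cnn1 were not among the 11, and Acta2 had an adjusted p of 0.076. Sox10, also in the list, went the other way without passing over all genes (142 ± 215 against 2.08 ± 5.03 CPM, adjusted p = 0.061). Jag2 lost its call in 8 of the 13 fits that each left out 1 line, with a log2 fold change of 2.57 in place of 3.29 without knockout replicate 2 (adjusted p = 0.051). The size varied among knockout lines, from 84.2 CPM of Krt5 in knockout replicate 6 to 12403 CPM in knockout replicate 2. That line also stood apart in genes of other identities. It held 4042 CPM of Vim, 2580 CPM of Acta2 and 80.0 CPM of Zeb1, against at most 704, 207 and 13.1 CPM in the other knockout lines, and 40.8 CPM of Epcam and 92.3 CPM of Cdh1, against at least 266 and 311 CPM.

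Luminal epithelial markers as a list did not pass the test (22 tested, 1 rose and 3 fell, 1 and 3 adjusted over the list alone, median -0.57, adjusted p = 0.12). With 1 line left out the median went from -0.84 to -0.31 and adjusted p from 0.054 to 0.43. The main luminal keratins fell. Krt18 was 2059 ± 318 CPM in WT and 857 ± 224 CPM in knockout lines, 2.40-fold lower (adjusted p = 0.0026), with all 7 knockout lines below every WT line. Krt8 was 1.96-fold lower (adjusted p = 0.047), a call kept in 3 of 13 fits that left out 1 line. Muc1 fell from 2.06 ± 2.40 to 0.208 ± 0.109 CPM, a call kept in 8 of 13 such fits (log2 fold change -2.60 in place of -3.29 without WT replicate 3), and Ly6d rose from 0.513 ± 0.363 to 58.3 ± 69.0 CPM (6.02 in place of 6.83 without knockout replicate 7). Among epithelial junction and identity genes (31 tested, 1 rose and 3 fell, 2 and 3 adjusted over the list alone, median -0.22, adjusted p = 0.088), the desmosomal genes Dsg2, Dsc2 and Pkp2 fell by log2 fold changes of -1.91, -1.84 and -0.58 (Pkp2 called in 4 of 13 such fits, Dsc2 in 12, not without knockout replicate 3), while Grhl3, a transcription factor of the epidermal barrier, rose 8.09-fold. This list passed the test without knockout replicate 6 (adjusted p = 0.037) and without knockout replicate 7 (adjusted p = 0.028), and in the other fits that left out 1 line adjusted p reached 0.50. Knockout replicate 2 had the lowest score of this list in its group.

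**Figure D3:**
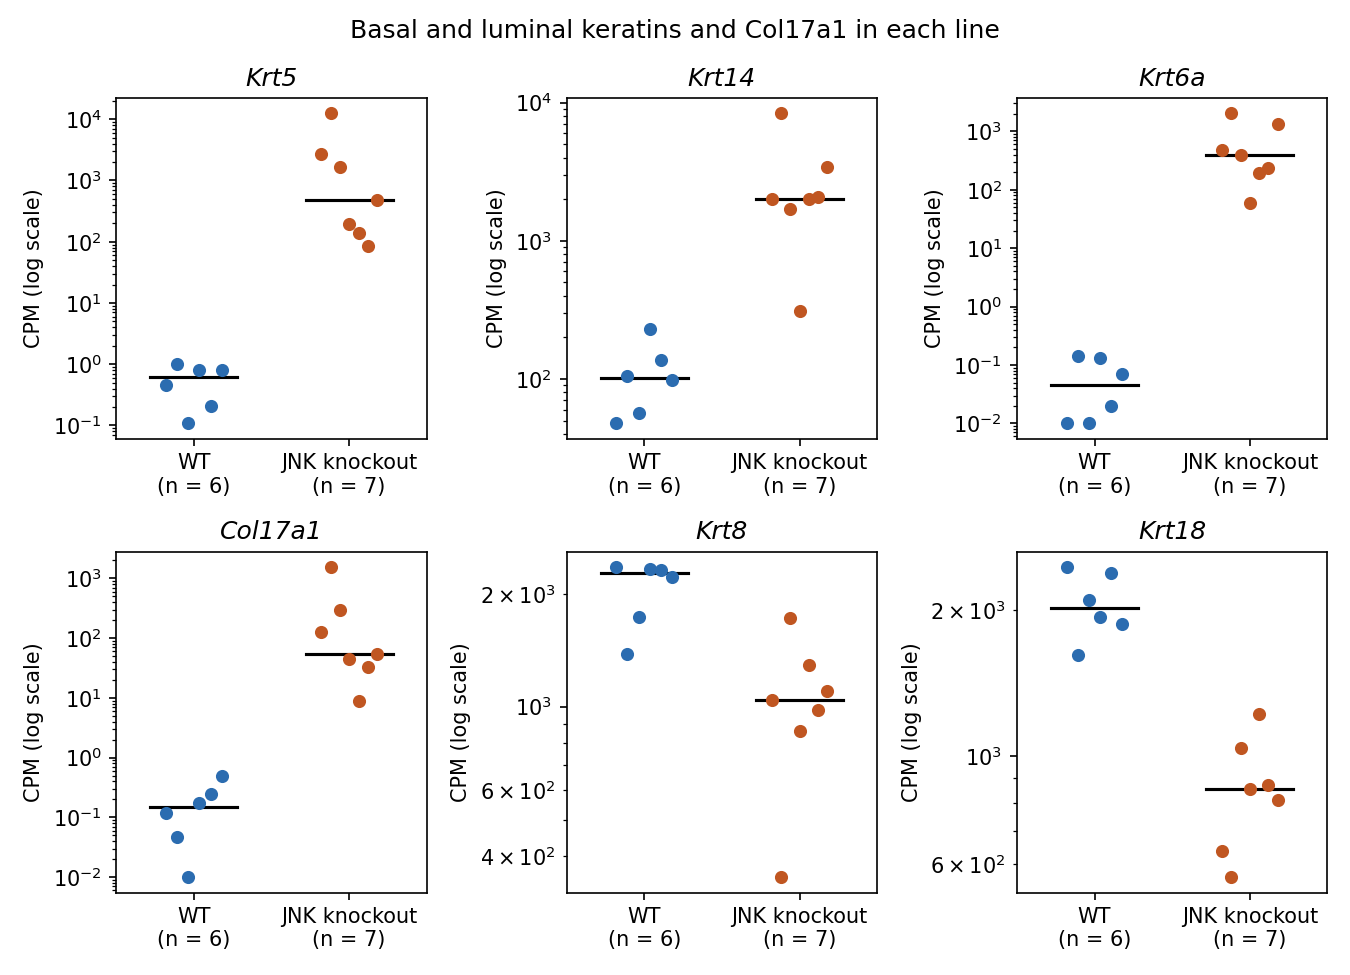
CPM on a log scale of the basal keratins Krt5, Krt14 and Krt6a, of Col17a1 and of the luminal keratins Krt8 and Krt18 in each line (points, values of 0 drawn at 0.01), with the group median (bar). The first 4 genes are higher in all 7 knockout lines than in all 6 WT lines, and Krt18 is lower in all 7.

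JNK pathway components fell as a list with the preset correlation. Of 21 tested pathway components 0 rose and 4 fell (0 and 7 adjusted over the list alone), with a median log2 fold change of -0.41 (adjusted p = 5.5e-06, and 0.13 with an estimated correlation). Mapk8 and Mapk9, which encode JNK kinases themselves, count among the 4. Without them the list of 19 still passed with a smaller median (-0.30, 0 rose and 2 fell, 0 and 4 adjusted over the list alone, adjusted p = 0.0041, and 0.36 with an estimated correlation). The others were Dusp16 and Dusp8, which encode phosphatases of JNK and p38 kinases. Dusp16 was 4.20-fold lower (145 ± 47.9 against 34.5 ± 15.4 CPM, adjusted p = 0.0030) and Dusp8 6.79-fold lower (35.7 ± 13.8 against 5.25 ± 3.36 CPM, adjusted p = 0.0031), both below every WT line in all 7 knockout lines. AP-1 and ATF transcription factors, among which are targets of JNK, did not move as a list (16 tested, 1 rose and 1 fell, also adjusted over the list alone, median -0.16, mean 0.09, direction of the test down, adjusted p = 0.80). Junb rose 1.63-fold (adjusted p = 0.019) and Atf3 was 3.65-fold lower (adjusted p = 0.030, called in 6 of 13 fits that left out 1 line). Immediate early genes did not pass either (22 tested, 2 rose and 2 fell, 3 and 5 adjusted over the list alone, median -0.35, adjusted p = 0.74). There Myc rose 1.62-fold, from 187 ± 34.1 to 304 ± 35.2 CPM, and Ier3 was 2.76-fold lower, each with all 7 knockout lines beyond the WT range in CPM. In TPM Myc was 182 and 177 in knockout replicates 1 and 5, below WT replicate 4 at 189. On log2(TPM + 1) neither Junb nor Myc was called.

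ERBB receptors and ligands did not pass the list test (16 tested, 1 rose and 2 fell, 2 and 4 adjusted over the list alone, median -0.18, adjusted p = 0.45). Lrig1, a negative regulator of ERBB receptors, was 1.86-fold lower, Lrig3 2.86-fold higher, and the ligand gene Epgn 5.47-fold lower. The call of Epgn was kept in 2 of 13 fits that left out 1 line. ERK feedback and output genes fell with the preset correlation (18 tested, 0 rose and 2 fell, 1 and 4 adjusted over the list alone, median -0.41, adjusted p = 0.039, but 0.46 with an estimated correlation and 0.061 in fry's directional test). The list call was lost without knockout replicate 5 (adjusted p = 0.092) or 6 (adjusted p = 0.10), and with 1 surrogate variable (adjusted p = 0.079). The feedback inhibitor gene Spry4 was 18.0 ± 24.1 CPM in WT, led by WT replicate 3 at 67.1 CPM, and 0.770 ± 0.790 CPM in knockout lines, and Etv5 was 3.91-fold lower but kept its call in 3 of 13 fits that left out 1 line. WT replicate 3 held 1166 CPM of Etv5, and without it the log2 fold change of Etv5 was -0.85 in place of -1.97 (adjusted p = 0.053) and that of Spry4 -3.41 in place of -4.54, which was -5.16 without knockout replicate 2.

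Interferon response genes fell as a list with the preset correlation. Of 38 tested members 0 rose and 5 fell (0 and 16 adjusted over the list alone), with a median log2 fold change of -1.58 (adjusted p = 1.4e-07, and 0.62 with an estimated correlation). With fry the list did not pass in the directional test (adjusted p = 0.18) or in the mixed test (adjusted p = 0.057). Without WT replicate 4 the median was -1.05. The 5 fallen members were Dtx3l, the RNA sensor gene Ifih1, Ifit2, Irf9, a subunit of the interferon-stimulated transcription factor complex, and Gbp7. Irf9 was 57.1 ± 30.6 CPM in WT and 21.8 ± 8.02 CPM in knockout lines, and Dtx3l 67.3 ± 18.9 against 35.1 ± 7.01 CPM (adjusted p = 0.012). The fall was not against each WT line. WT replicate 2 lay within the range of the knockout lines for Dtx3l, Ifih1, Ifit2 and Irf9 (40.5, 11.7, 10.8 and 15.8 CPM), as did WT replicate 3 for Ifit2 (17.7 CPM). The single-gene calls of Ifit2, Irf9 and Ifih1 held in 4, 5 and 7 of 13 fits that left out 1 line. With WT replicates 4 and 5 summed the list still passed (adjusted p = 1.2e-06), but 2 of its members were called. Antigen presentation genes fell as well with the preset correlation (18 tested, 0 rose and 4 fell, 1 and 8 adjusted over the list alone, median -0.55, adjusted p = 0.0039, and 0.58 with an estimated correlation). In fry's directional test they did not pass (adjusted p = 0.11). B2m, the light chain of class I molecules, was 2.18-fold lower, Erap1, an aminopeptidase that trims peptides for them, 1.87-fold lower, Nlrc5, their transactivator, lay at 7.79 ± 9.27 against 0.556 ± 0.207 CPM, and H2-DMb1, part of the complex that loads class II molecules, 6.87 ± 5.95 against 1.12 ± 0.693 CPM. The calls of Nlrc5, B2m, H2-DMb1 and Erap1 held in 2, 4, 9 and 11 of 13 such fits, and the log2 fold change of Nlrc5 was -2.96 in place of -3.80 without WT replicate 4. In WT replicates 2 and 3 Nlrc5 was 0.070 and 0.054 CPM, below every knockout line (at least 0.314 CPM). Cytokines, chemokines and NF-kappaB targets went both ways (30 tested, 3 rose and 1 fell, 4 and 1 adjusted over the list alone, median 0.01, mean 0.29, direction of the test down, adjusted p = 0.80). Cxcl5 rose 13.8-fold, Il33 13.3-fold and Il1a from 0.277 ± 0.177 to 32.4 ± 69.7 CPM, of which 190 CPM were in knockout replicate 1, while Tslp fell from 26.7 ± 39.5 to 0.641 ± 0.496 CPM. Without knockout replicate 1 the log2 fold change of Il1a was 4.45 in place of 6.84 and that of Il33 3.14 in place of 3.73. That of Il33 was 4.78 without WT replicate 5, and that of Tslp -4.09 in place of -5.37 without WT replicate 4.

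The lists of matrix genes and of adhesion genes passed the test downwards with the preset correlation, and that of matrix proteases did not. Of 42 tested collagens and other matrix genes 1 rose and 6 fell, also adjusted over the list alone (median -0.61, adjusted p = 0.019, and 0.69 with an estimated correlation). The median was -0.21 without WT replicate 3. The call of the list was lost without knockout replicate 5, 6 or 7 (adjusted p = 0.087, 0.074 and 0.051), and with the trend of each library with gene length removed (adjusted p = 0.055). Loxl1, an enzyme of collagen and elastin crosslinking, was 10.6-fold lower, Efemp2 (fibulin-4) 4.31-fold lower and Efemp1 (fibulin-3) 13.9-fold higher, each in all 7 knockout lines. Col1a1 was 184 CPM in WT replicate 3 and at most 9.46 CPM in the other WT lines, and lost its call without that line (log2 fold change -1.91 in place of -4.40, adjusted p = 0.053) and, more narrowly, without knockout replicate 1 or 7. Integrins and focal adhesion genes fell with the preset correlation (31 tested, 2 rose and 4 fell, 2 and 6 adjusted over the list alone, median -0.26, and -0.50 without knockout replicate 2, adjusted p = 0.0049, and 0.58 with an estimated correlation). In fry's directional test neither the matrix list (adjusted p = 0.25) nor the adhesion list (adjusted p = 0.099) passed. Ptk2, which encodes focal adhesion kinase, was 2.10-fold lower and Itga7 lower by a log2 fold change of -2.68, while Tns4 was 9.17-fold and Cav1 3.30-fold higher. Matrix proteases and inhibitors did not pass (30 tested, 3 rose and 4 fell, 3 and 7 adjusted over the list alone, median -0.29, adjusted p = 0.30). In that list Timp3, an inhibitor of metalloproteinases, was 9.45-fold higher and Mmp14, a membrane metalloproteinase, 8.14-fold higher, whereas Adamts1 was 12.0-fold and Mmp24 20.8-fold lower (log2 fold change -5.15 in place of -4.38 without knockout replicate 4).

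TGF-beta and BMP pathway genes fell with the preset correlation (29 tested, 1 rose and 5 fell, 1 and 7 adjusted over the list alone, median -0.40, adjusted p = 0.0025, and 0.13 with an estimated correlation). Bmp1, a procollagen protease despite its name, had a log2 fold change of -1.58 (274 ± 56.1 against 91.4 ± 30.5 CPM) and Ltbp3, which binds latent TGF-beta, 2.32-fold lower (adjusted p = 0.0045), both in all 7 knockout lines. Pmepa1 and Inhbb were 2.09-fold and 4.14-fold lower (Inhbb called in 9 of 13 fits that left out 1 line), and Skil also fell, while Bmp7 rose from 0.926 ± 1.23 to 14.0 ± 11.5 CPM. Mesenchymal transition genes did not move as a list in the 13 lines (21 tested, 1 rose and 1 fell, also adjusted over the list alone, median 0.15, mean 0.50, direction of the test down, adjusted p = 0.40). Without knockout replicate 2 the list passed the test downwards with a negative median (-0.45, adjusted p = 0.033), while without other single lines adjusted p reached 0.74. The risen member, Tgfbi, was 368 CPM in that line and at most 13.2 CPM in the other knockout lines, and its log2 fold change was 7.35 with and 3.83 without that line. Nt5e was 3.20-fold lower but kept its call in 3 of 13 fits that left out 1 line. Fibroblast markers did not pass (10 tested, 0 rose and 2 fell, also adjusted over the list alone, median -0.85, adjusted p = 0.081), the falling members being Col1a1 and Col1a2. Over the 13 fits that left out 1 line adjusted p of that list went from 0.017 to 0.13 and its median from -1.98 (without knockout replicate 2) to -0.30 (without WT replicate 3). It passed without WT replicate 1, knockout replicate 2 or knockout replicate 3 (adjusted p = 0.029, 0.017 and 0.037), with no filter on low counts (adjusted p = 0.047) and without both WT replicate 3 and knockout replicate 2 (adjusted p = 0.0094). YAP and TAZ targets did not pass (23 tested, 1 rose and 2 fell, also adjusted over the list alone, median 0.13, adjusted p = 0.80), with F3 3.43-fold lower, called in 9 of 13 such fits, and Foxf2 at 0.443 ± 0.290 against 9.75 ± 17.4 CPM, called in 2 (log2 fold change 2.97 in place of 4.45 without knockout replicate 2, adjusted p = 0.081).

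Targets of p53 rose as a list with the preset correlation. Of 29 tested members 6 rose and 0 fell (10 and 1 adjusted over the list alone), with a median log2 fold change of 0.63 (adjusted p = 2.4e-05, but 0.46 with an estimated correlation and 0.051 in fry's directional test). Cdkn1a, which encodes the cell cycle inhibitor p21, was 312 ± 117 CPM in WT and 617 ± 143 CPM in knockout lines (1.98-fold, adjusted p = 0.031, called in 9 of 13 fits that left out 1 line). Perp, which is also a desmosomal gene, rose 2.56-fold, Ccng1 2.27-fold (called in 10 of 13 such fits) and Sesn2 2.85-fold. On log2(TPM + 1) Cdkn1a, Ccng1 and Sesn2 were not called, while Perp was. Sesn2 lies on chromosome 4. The joint list of ATF4 and unfolded protein response genes rose with the preset correlation (29 tested, 5 rose and 0 fell, 9 and 0 adjusted over the list alone, median 0.39, and 0.59 without WT replicate 3, adjusted p = 0.0015, but 0.46 with an estimated correlation and 0.061 in fry's directional test). Genes of the unfolded protein response such as Hspa5, Hsp90b1, Herpud1 and Calr were not among the 5. The risen members were mostly enzymes of amino acid and one-carbon metabolism, with Shmt2 1.88-fold, Mthfd2 2.07-fold and Asns 2.13-fold higher (Asns called in 9 of 13 such fits), together with Aldh18a1 and Sesn2, which 2 lists share. NRF2 targets did not pass (30 tested, 2 rose and 0 fell, also adjusted over the list alone, median 0.22, adjusted p = 0.088), though Ftl1 rose 2.69-fold and Gstm2 2.71-fold. With 1 line left out adjusted p of that list went from 0.018 to 0.37. It passed without WT replicate 4 (adjusted p = 0.018), without knockout replicate 3 (adjusted p = 0.037) and with WT replicates 4 and 5 summed (adjusted p = 0.035).

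The proliferation genes did not pass the test with all 13 lines as separate samples (34 tested, 0 rose and 0 fell, also adjusted over the list alone, median -0.25, adjusted p = 0.055). At an unadjusted p under 0.05 edgeR had 3 members, all lower, and DESeq2 called 0 and limma-voom 0 after adjustment. The list passed in the 7 fits without WT replicate 3, 4 or 5 or knockout replicate 1, 3, 4 or 5, with adjusted p from 0.00037 to 0.037, and not in the other 6, with adjusted p from 0.094 to 0.48. It also passed with WT replicates 4 and 5 summed (adjusted p = 0.0058), with no filter on low counts (0.020) and with the length trend removed (0.046), but not without both WT replicate 3 and knockout replicate 2 (0.14), with 1 surrogate variable (0.076) or with an estimated correlation (0.84). The median was negative in each. Mki67 was 216 ± 95.9 CPM in WT and 130 ± 42.7 CPM in knockout lines (adjusted p = 0.16), and E2f1 52.2 ± 14.8 against 33.8 ± 13.5 CPM (adjusted p = 0.17). Cell cycle inhibitors and senescence genes held 1 risen member, Cdkn1a, of 17 tested (1 rose and 2 fell adjusted over the list alone, median -0.08, mean 0.02, direction of the test up, adjusted p = 0.93). Of 17 BCL2 family genes 1 rose and 1 fell, also adjusted over the list alone (median 0.09, adjusted p = 0.73). These were Bad, 1.69-fold higher, and Bcl2l11, the gene of the death activator BIM, 1.79-fold lower with all 7 knockout lines below every WT line (adjusted p = 0.0082). Among 35 autophagy genes Atg4b rose 1.56-fold and Atg16l2 was 1.65-fold lower, and the list did not pass (1 rose and 1 fell, 1 and 1 adjusted over the list alone, median 0.08, adjusted p = 0.32). Of 13 fits that left out 1 line, 5 called Bad, 7 Atg4b and 5 Atg16l2.

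Notch pathway genes did not pass the list test (17 tested, 1 rose and 2 fell, 2 and 2 adjusted over the list alone, median -0.62, adjusted p = 0.090), but passed without WT replicate 3 (adjusted p = 0.047), without WT replicate 4 (adjusted p = 0.049) and without both WT replicate 3 and knockout replicate 2 (adjusted p = 0.041). Without other single lines adjusted p reached 0.26. The Notch target Nrarp was 2.82-fold lower and the ligand gene Dll1 4.71-fold lower. WT replicate 3 held 389 CPM of Dll1, and without it the log2 fold change of Dll1 was -1.44 in place of -2.24 (adjusted p = 0.032). The list of Wnt target genes, which also holds ligands, receptors and inhibitors, did not pass either (26 tested, 2 rose and 0 fell, also adjusted over the list alone, median 0.38, adjusted p = 0.088). It passed in 5 of 13 fits that left out 1 line, without WT replicate 2, 4 or 5 or knockout replicate 3 or 5 (adjusted p from 0.025 to 0.046, and up to 0.16 in the others). Over these 13 fits its median went from 0.13 to 0.55. The list also passed with WT replicates 4 and 5 summed (adjusted p = 0.043), with no filter on low counts (0.047) and with the length trend removed (0.047). The ligand gene Wnt4 rose 20.9-fold (1.09 ± 0.412 against 22.8 ± 13.6 CPM, adjusted p = 0.00065) and Notum, a secreted Wnt inhibitor, 10.1-fold, a call kept in 3 of 13 fits. Both were higher in all 7 knockout lines than in any WT line. Cholesterol synthesis genes fell as a list with the preset correlation (24 tested, 0 rose and 1 fell, 1 and 7 adjusted over the list alone, median -0.27, adjusted p = 0.012, but 0.66 with an estimated correlation and 0.12 in fry's directional test). Without knockout replicate 2 the adjusted p of the list with the preset correlation was 0.051. Dhcr7, the enzyme of the last step to cholesterol, was 3.38-fold lower, a call kept in 4 of 13 fits that left out 1 line (log2 fold change -2.37 in place of -1.76 without knockout replicate 6). Hypoxia and glycolysis genes did not pass (30 tested, 0 rose and 1 fell, also adjusted over the list alone, median -0.04, mean -0.08, direction of the test up, adjusted p = 0.80). The fallen gene was Car9, 6.95-fold lower, which narrowly lost its call without WT replicate 3 (adjusted p = 0.050) and had a log2 fold change of -3.46 in place of -2.80 without knockout replicate 5. Without WT replicate 3 that list passed with a median of 0.40 (adjusted p = 0.016), and without other single lines adjusted p reached 0.99. Milk protein genes did not pass (11 tested, 0 changed, 0 adjusted over the list alone, 4 at an unadjusted p under 0.05 in edgeR, 2 with DESeq2 and 0 with limma-voom after adjustment, median -0.55, adjusted p = 0.74). Csn3 was 11993 CPM in WT replicate 3 and 1658 CPM in WT replicate 2 (2298 ± 4794 in WT and 21.4 ± 46.9 CPM in knockout lines, adjusted p = 0.11), and Ltf was 136 ± 142 against 2735 ± 3942 CPM (adjusted p = 0.059).

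Together 11 of the 30 lists passed the test with the preset correlation, 3 upwards and 8 downwards. With correlations estimated from the lists' own genes 0 passed, and 52 of 100 splits of the 13 lines, the real one included, gave 11 or more lists. The directional test of fry, which compares no list with other genes, passed 5 lists (basal markers, JNK pathway, TGF-beta and BMP, Wnt ligands, receptors and targets, and Notch). Marker lists of 5 other cell types had low medians. Medians over the members of each list of the group mean were 0.016 and 0.075 CPM in WT and knockout lines for endothelial, 0.037 and 0.029 for macrophage and leukocyte, 0 and 0 for lymphocyte, 0.0037 and 0.0037 for adipocyte, and 0.52 and 0.082 for pericyte and smooth muscle markers. None of the 11 members of these lists that could be tested changed. The highest single values were 554 CPM of Cd14 in knockout replicate 1 and 212 CPM of Notch3 in WT replicate 3, genes that epithelial cells can also express. Acta2 and Vim, which smooth muscle and mesenchymal cells express and which stand in the basal and mesenchymal lists, were not near 0 in each line. Acta2 was 2580 CPM in knockout replicate 2 and Vim 4042 CPM there and 654 CPM in WT replicate 3.

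**Figure D4:**
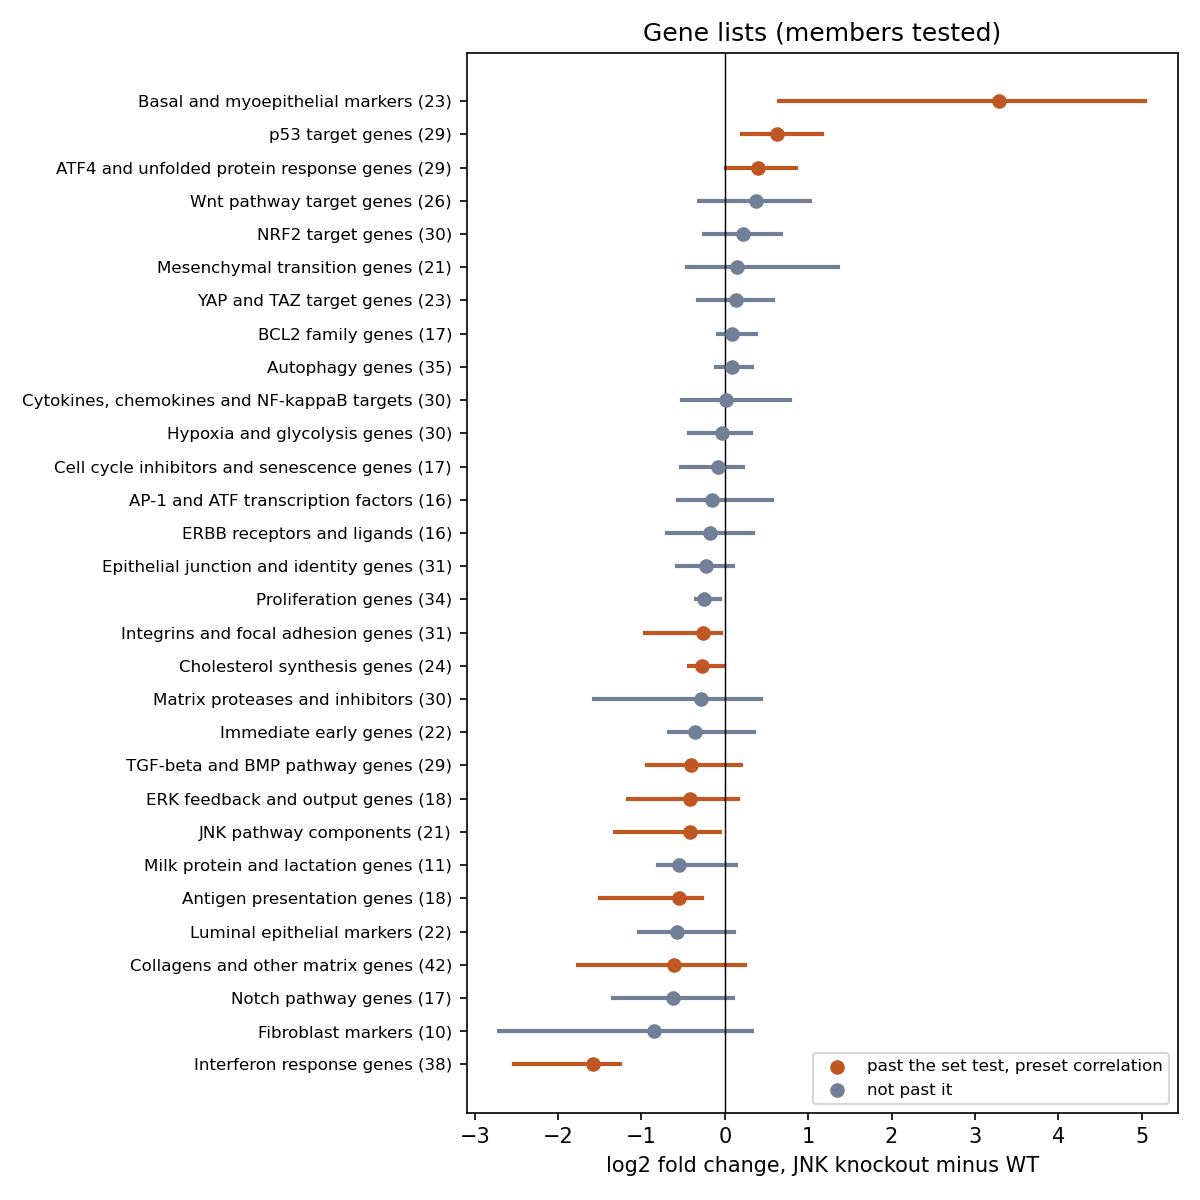
Median log2 fold change (knockout minus WT, points) and the interquartile range of the members (bars) of the 30 tested gene lists, with the number of members tested. Lists past the set test with the preset correlation are in orange, 3 to the right of 0 and 8 to the left.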

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

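Values in single lines that stood apart from their group were searched for among the named genes, list scores, library measures and distances, with Dixon's ratio of the gap to the range. Of 262 groups of values 15 stood out, where chance alone gives about 13.1, so no single flag carries much weight. WT replicate 3 accounted for 6 of them. It was high in Col1a1 (ratio 0.644), Rtn1 (0.746), Spry4 (0.771) and the share of counts in its 10 most abundant genes (0.809, with 8.19% against a WT median of 4.58%), and low in Perp (0.629) and in the score of matrix proteases and inhibitors (0.692). Knockout replicate 2 accounted for 4, with Tgfbi high (0.573), Pkp2 low (0.575), the score of epithelial junction and identity genes low (0.606), and a high mean distance to its own group (0.678).

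WT replicate 2 was high in Mapk9 (0.696) and, among values near 0, in Krt6b (0.723). Knockout replicate 5 was low in Mapk9 (0.696 of the range of the knockout lines), knockout replicate 4 was high in Mmp24 (0.671), and WT replicate 4 was the only WT line with reads of Pitx1 (1.00).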

How the results depend on the processing

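The fits without both outlying lines (WT replicate 3 and knockout replicate 2) and with the gene length trend removed, and the JNK pathway list without Mapk8 and Mapk9, which left 11 lists past the set test, were chosen after the data were seen. Mapk8 and Mapk9 stayed lower and past the threshold in each alternative run, with log2 fold changes from -2.48 to -2.02 and from -1.75 to -1.51. The separation of the groups also kept its direction and call. Leaving out 1 line gave 324 to 649 higher genes, 316 to 592 lower genes, 10 to 15 lists past the set test, log2 fold changes of -2.48 to -2.30 for Mapk8 and -1.69 to -1.51 for Mapk9, a separation of 25.6 to 31.1, and a spread difference of -13.3 to 4.93.

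DESeq2 called 1130 higher and 977 lower genes, among them 1099 of the 1111 changed genes. Voom with sample weights called 1421 and 1411. A threshold of 0.01 left 96 and 116, and a minimum log2 fold change of 1 left 312 and 363. The last 2 are subsets by construction, and for the others the cause was not tested. With 1 surrogate variable 878 genes were higher. On log2(TPM + 1) 286 genes were higher and 998 lower, and on log2(TPM + 0.1) 322 and 981, so the share of higher genes among the calls dropped from 50.9% to 22.3% and 24.7%. TPM forces equal sums over length-scaled values, and the cause of the shift was not tested further. Without both outlying lines 492 and 522 genes were called, sharing 761 with the main calls, and with the length trend removed 546 and 518, sharing 906, all shared genes with the same sign. The set test gave 0 lists with estimated correlations, 5 with fry's directional test and 24 with its mixed test, which ask other questions.

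The spread difference turned positive over all tested genes (4.17). Among the named genes 0 turned. Medians of 6 lists, none of them past the test in the 13 lines, turned sign, and the cause was not tested. Cytokines, chemokines and NF-kappaB targets gave -0.0387 with library size only, -0.000997 with the stricter filter, -0.0456 without both outlying lines and -0.0173 with the length trend removed, and -0.20 to 0.15 with 1 line left out. Hypoxia genes gave 0.0609 with no filter, 0.14 with 1 surrogate variable and 0.37 (adjusted p = 0.041) without both outlying lines, and -0.16 to 0.40 with 1 line left out. Cell cycle inhibitors and senescence genes gave 0.00473 with the stricter filter and -0.20 to 0.0251 with 1 line left out. Mesenchymal genes gave -0.41 (adjusted p = 0.016) and YAP and TAZ targets -0.23 without both outlying lines, with ranges of -0.45 to 0.32 and -0.0821 to 0.23 with 1 line left out, and AP-1 factors ranged from -0.34 to 0.0176. Of the 90 named genes past the threshold, 60 kept the call in each leave-one-out fit that could test them, 38 in each alternative run, and 34 lost it with limma-voom. With WT replicates 4 and 5 summed 14 of the 90 lost it. Of 23845 genes 13058 had enough reads for the test, Mapk10 did not, and 5 lists of other cell types had too few such members. For these, lack of expression and limits of depth were not separated, and no fit varied the depth.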

Other observations

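Chosen after values had been seen were the genes and families of the first 2 paragraphs, the choice of chromosome 4, and the tests of single lines behind chromosome 4, gene length and the basal genes, of the length trend, and of neighbouring genes near 0.

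Several genes of stratified and keratinizing epithelium were higher in knockout lines, and others were not. Of 20 tested keratin genes 9 were higher and 2 lower in knockout lines (Fisher's exact p = 5.5e-08 for the excess of higher genes, adjusted p = 5.5e-07, with 8 to 9 higher and 1 to 2 lower under other scalings), and all 4 tested small proline-rich genes, components of the cornified envelope, were higher (adjusted p = 2.3e-05). Of the keratins 11 belong to the basal or luminal lists, 6 of the 9 higher ones among them. Outside the lists 3 of 9 tested keratins were higher (Krt4, Krt75 and Krt79, Fisher's exact p = 0.0052, adjusted p = 0.026). The families were picked from 20 looked at, of which 4 passed after adjustment, the others being ribosomal protein and serpin B genes, of which serpin B did not pass outside the lists (adjusted p = 0.17). Kallikrein genes (6 tested, 0 changed) and histocompatibility genes (18 tested, 0 higher and 2 lower) were among those that did not pass. The test treats genes as independent, which family members are not. The families were also chosen after the same values had been seen. These p-values, those outside the lists included, therefore describe the excess and are no independent test of it. Krt4, a keratin of lining epithelia, was 0.145 ± 0.113 CPM in WT and 17.1 ± 16.6 CPM in knockout lines, and Ivl (involucrin) 0.234 ± 0.156 against 4.45 ± 4.07 CPM. Sprr1b, Krtdap and Dsg1b had 0 reads in the WT lines, and were at least 333-fold, 377-fold and 191-fold higher in the knockout lines. Krt10, a keratin of suprabasal epidermis, was 2.00 ± 0.347 against 2.51 ± 0.759 CPM and did not pass the test (adjusted p = 0.47), and its partner Krt1, with 7 reads over the WT and 205 over the knockout lines, had too few reads for the test. The late epidermal gene Lor was 0.756 ± 0.598 against 1.35 ± 1.85 CPM and did not pass the test (adjusted p = 0.62). Desmosomal cadherins moved in opposite directions, with Dsc3 and Dsg1b higher and Dsc2 and Dsg2 lower.

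Genes that varied little among WT lines and fell included the tetraspanin gene Tspan7 (84.8 ± 5.60 against 6.57 ± 3.40 CPM), the semaphorin receptor gene Plxnb1 (186 ± 9.18 against 78.4 ± 17.4 CPM) and the semaphorin gene Sema4c (32.1 ± 4.60 against 13.9 ± 2.22 CPM), and Limk2, a kinase of the actin cytoskeleton, rose from 47.1 ± 5.64 to 204 ± 64.4 CPM. Each separated all 7 knockout lines from all WT lines. The p38 kinase gene Mapk14 was also lower (110 ± 8.09 against 83.6 ± 11.8 CPM, adjusted p = 0.037). WT replicate 2 had 0 to 5 reads of Cdkn2a, Cdkn2b and Mtap, neighbours on chromosome 4 (89137370 to 89311032), and with Klhl9 these genes reached at most 0.117 CPM in that line against means of at least 50.6 CPM in the others. A scan of each line for 3 or more neighbouring expressed genes far below the mean of the other lines found 9 other runs, at 5 distinct places. Of these, 5 were the run from Krt6b to Krt5 in 5 WT lines, so not of 1 line, and 1 reached 7.35 CPM in its line, so not near 0. This left 3 runs near 0 in 1 line alone. The scan thus counted more than it was meant to, its bound of 5 other places gives different answers by count, and a loss of the region stays open. Knockout replicate 6 held 4.05 CPM of Cdkn2a and 4.07 CPM of Cdkn2b. Genes of chromosome 12 had a median of -0.79 in knockout replicate 6 relative to the mean of all lines on the log2 scale.

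The counts of 566 higher and 545 lower genes were each reached by 1 of 100 splits of the lines, the real one, and the other splits gave at most 39 and 40, so chance assignment of lines can be excluded for them. For the 11 lists it cannot, since 52 of the 100 splits gave as many and the highest of the others gave 20.

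Basal genes were higher in knockout lines as a group with the preset correlation, but not with an estimated one (adjusted p = 0.36), and several technical sources were set against the rise. Of the 11 raised members of the list, 9 stayed called without knockout replicate 2, the line with the highest levels, and 10 with the length trend removed, which argues against either as the whole source. Cells with an intact Mapk8 gene mixed into the cultures would bring Mapk8 reads with basal transcripts. Over the 7 knockout lines the basal score and log2 Mapk8 had a Pearson r of -0.18 (exact permutation p = 0.71) and a Spearman rho of -0.11 (p = 0.84), and r was -0.07 without the 2 lines farthest from the median of Mapk8, which is too few lines to decide, so such a mixture stays open. A difference in the tumours or cells that founded the lines may also account for the rise, cannot be told apart from the genotype in this design, and was not tested.

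Genes of chromosome 4 tended to be higher in knockout lines, but not in each of them. Relative to the mean of all lines, their median was 0.33 to 0.50 in knockout replicates 1, 2, 3 and 7, 0.04 and 0.03 in replicates 4 and 5 and -0.30 in replicate 6, against -0.34 to -0.08 in the WT lines. Other chromosomes shifted by less, of which 2 had smaller p-values than chromosome 4 besides X. The shift from all genes was 0.19 for chromosome 11 (exact permutation p = 0.0052, adjusted p = 0.052) and 0.12 for chromosome 10 (p = 0.014, adjusted p = 0.084), and for chromosome 2, with 81 lower genes of 982, it was -0.18 (p = 0.026, adjusted p = 0.10). Of 769 tested genes 113 (14.7%) were higher and 9 lower, against 4.33% higher over all genes, and the median log2 fold change was 0.41. The shift did not exceed the variation among lines after correction for 20 chromosomes (exact permutation p = 0.017, adjusted p = 0.084), whereas that of the X chromosome, -0.18, did (p = 0.00058, the smallest these splits can give, adjusted p = 0.012). The chromosome 4 median stayed 0.40 above that of all genes with the length trend removed and at least 0.34 above it without any single line, and the lowest of 4 parts of the chromosome lay 0.17 above it, so neither gene length nor a single line is the whole source and a concentration in part of the chromosome stays open. In 8 of 13 lines the first and last 2 parts shifted in the same direction. That met the bound set beforehand against a copy number change of the whole chromosome, but the exact 95% interval of this share (31.6% to 86.1%) includes the 84.6% that such a change was taken to need, so it stays open, and changes of segments, which may also underlie the pattern, were not tested.

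Short genes tended to be higher and long genes lower in knockout lines, with a Spearman coefficient of -0.26 across genes, which are not independent replicates. The shortest 10% of genes had a median log2 fold change of 0.28 and the longest 10% one of -0.20. Knockout replicate 5 differed most, with a gap (shortest minus longest, relative to the mean of all lines) of 1.49 between these groups of genes. The gap lay between -0.52 and 0.06 in the WT lines and between -0.19 and 0.24 in the other knockout lines. The coefficient without knockout replicate 5 was still -0.15, so that library is not the whole source. With the trend of each library removed, 81.5% of the changed genes stayed called, which argues against the trend as the source of most calls. Of 80 ribosomal protein genes 21 were higher (median 0.58) and 14 (median 0.24) with the trend removed. Without knockout replicate 5 there were 26 (median 0.39). Whether RNA quality or regulation may lie behind the remaining trend cannot be settled from gene counts.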
